A study of Peromyscus polionotus with 11 samples.

How the data were processed

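Total RNA from micropunches of the brain of the oldfield mouse (Peromyscus polionotus) was labelled with biotin and hybridised to 11 arrays carrying Affymetrix probe sets designed for the house mouse. Per the labels, the punches came from the medial preoptic area (3 long-day and 3 short-day samples) and from the bed nucleus of the stria terminalis (3 long-day and 2 short-day samples). The labels' protocols name a column kit for the extraction. The groups and the sample numbers were taken from the sample descriptions. These do not tie the samples to named animals or say whether a number shared by both nuclei marks the same animal. The p-values therefore measure the spread between these samples.

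The deposited values are probe set intensities on a linear scale. Per the submitters' processing notes they were made with RMA version 3.4; other steps are not given in the sources used here. The deposited values are whole numbers, and every array has a median intensity of 19, so they had been normalized between arrays and rounded. Because the probes were designed for another species, sequence differences between the house mouse and the oldfield mouse lower the signal of some probe sets by an unknown amount. Apart from their place above or below the array median, levels of different probe sets were therefore not compared with each other. The loss was taken to be shared by all arrays, which was not tested. Of all values, 51.1% were 19 or less. A step of 1 intensity unit is 0.07 on the log2 scale at 19 and larger below it. No detection call was used. The number of arrays limits the precision.

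The table held 22690 probe sets. After 64 control probe sets were set aside, 22626 were tested. Gene names came from the platform annotation supplied with the probe table: 20380 of the tested probe sets carry exactly 1 gene symbol (12393 genes), 691 carry several and 1555 carry none. Only probe sets with 1 symbol were named. Some symbols in that annotation can be old. Some genes are not reported here.

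The log2 of the deposited intensities was taken with no pseudocount, since no value was 0. A linear model with 4 group means was fitted to all 11 arrays with lmFit and eBayes of limma 3.58.1 in R 4.3.3, which left 7 residual degrees of freedom and gave 12.9 prior degrees of freedom. There were 5 comparisons: short minus long day in the medial preoptic area, the same in the bed nucleus, the mean of these, their difference, and bed nucleus minus medial preoptic area. Tests were two-sided, and p-values were adjusted with the Benjamini-Hochberg method over all probe sets, with a threshold of 0.05. Differences are given on the log2 scale with the standard error of the model, and group levels as mean intensity ± SD.

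Before the data were examined, 20 gene lists, the comparisons, the alternatives and the rule for naming genes were fixed. The lists were tested with limma's camera at a preset correlation between genes of 0.01, on 1 probe set per gene (that with the highest mean), adjusted over the lists within a comparison. An estimated correlation and the self-contained test fry were run beside it. The rule for names was: where at least 24 genes passed, the 12 with the largest positive and the 12 with the largest negative difference among them, and otherwise all that passed, filled up to 24 by the smallest p. For the difference between the nuclei the limit was 12. List members that passed over all probe sets or over the list alone, the 4 members with the smallest p of each list that passed, and 17 genes of steroid, peptide and photoperiod biology were named in addition. Genes in the text are a selection from those the rule gives, and genes named outside it are said to be so.

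The procedure was tested on simulated arrays built from the real means and residual spreads, rounded to whole numbers, with 200 changed probe sets. The changed probe sets were all drawn from those with a mean above the median, so the shares found do not cover dim probe sets. With all 22626 probe sets tested, a log2 change of 1 was found in 88.6% of cases in the medial preoptic area, 87.6% in the bed nucleus and 97.9% between the nuclei. A change of 0.5 was found in 26.4%, 11.7% and 63.3% of cases in the same order. Of the calls, 4.73%, 6.99% and 4.56% were false. A change of -0.3 in the striatal list on 12393 genes in the medial preoptic area was found in 20 of 20 draws, and other lists were called in 2 of 380 tests. The simulated noise was independent between genes, whereas the estimated correlation between the striatal genes on the real arrays was 0.353. These draws therefore do not show how often lists of genes that vary together are called falsely.

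The alternatives were quantile normalization, centring on the median, a filter on dim probe sets, a trended and robust prior, array weights, 1 probe set per gene, a threshold of 0.10, the arrays of a nucleus alone, each array left out in turn, and a block on the sample number. Uniform noise that undoes the rounding was added as an alternative after the data had been examined. Per-array measures were compared between day lengths with exact two-sided permutation tests in a family of 46. The smallest p such tests can give here is 0.1.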

Results

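Gene expression was measured on 11 arrays in micropunches of 2 interconnected forebrain nuclei of the oldfield mouse, a North American deer mouse relative, kept in long or short days. The medial preoptic area, a hypothalamic region that controls parental and sexual behaviour, gave 3 long-day and 3 short-day samples. The bed nucleus of the stria terminalis, a relay between amygdala and hypothalamus that takes part in social and defensive behaviour, gave 3 long-day and 2 short-day samples. Both nuclei are rich in receptors for sex steroids, and the question was whether day length changes gene expression in them. All arrays had a median intensity of 19 and quartiles of 13 to 14 and 33 to 35. The first principal component held 23.2% of the variance. On it, the short-day medial preoptic array numbered 6 lay at -31.2, outside the range of the other 10 arrays (-6.63 to 25.4).

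In the bed nucleus, short days went with lower signal of 6 named genes and higher signal of 3. Lhx2, a LIM homeodomain transcription factor of forebrain development, had a mean intensity of 151 ± 10.4 (SD, n = 3) in long days and 62.5 ± 3.54 (n = 2) in short days. This is a log2 difference of -1.27 ± 0.16 (SE, adjusted p = 0.00415, limma). Cd24a, a cell surface glycoprotein of immature neurons and ependymal cells, fell from 715 ± 210 to 193 ± 12 (-1.85 ± 0.27, adjusted p = 0.0125, limma). Vim, the intermediate filament protein vimentin of glia, ependyma and vessels, fell from 154 ± 22.4 to 68.5 ± 3.54 (-1.16 ± 0.20, adjusted p = 0.0407, limma). Nptx2, a secreted pentraxin that binds glutamate receptors at synapses, fell from 52.3 ± 14.4 to 23.5 ± 2.12 (-1.12 ± 0.19).

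The other lower genes were Mycn, a transcription factor of the Myc family (log2 difference -0.95 ± 0.17, adjusted p = 0.0407, limma), and Mycbp, which encodes a Myc-binding protein (-0.79 ± 0.14, adjusted p = 0.0494, limma). Higher in short days were Igha, the immunoglobulin alpha constant region (1.07 ± 0.18), Nrros, a regulator of TGF-beta activation in myeloid cells (0.83 ± 0.15), and Rela, the p65 subunit of NF-kappa-B (0.79 ± 0.14). The adjusted p was 0.0384 for Igha, 0.0424 for Nrros and 0.0424 for Rela. Together with a probe set that carries no gene symbol, 10 of 22626 probe sets passed, 4 higher and 6 lower. Hmgb2, a chromatin protein of dividing cells, was at -0.96 and did not pass (adjusted p = 0.0540).

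**Figure D1:**
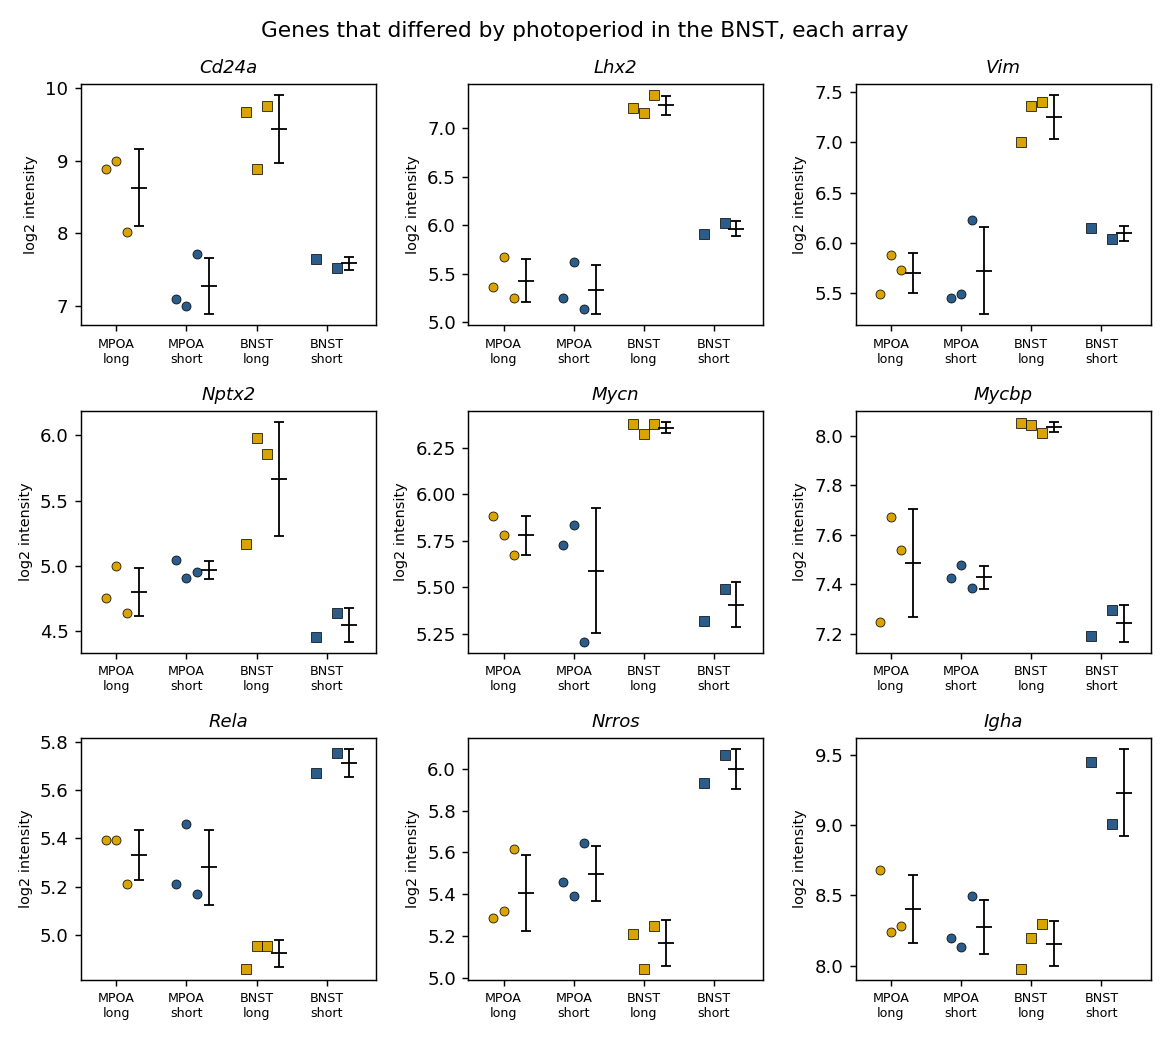
Log2 intensity (vertical axes) of the 9 genes that passed in the bed nucleus (BNST) on each of the 11 arrays, with the medial preoptic area (MPOA) beside them; points are arrays, yellow for long and blue for short days, and the bar beside each group is its mean with the SD. Lhx2 is at a mean intensity of 151 on the long-day and 62.5 on the short-day bed nucleus arrays; axes start above 0.

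Not all probe sets of these genes moved alike. The further Cd24a probe sets gave -0.97 (adjusted p = 0.0606) and -0.08, the further Vim probe sets -0.76 and -0.49, and the further Mycn probe sets -0.19 and 0.05. The further Igha probe sets gave -0.02 and -0.00, and the further Nptx2 probe set gave 0.15. The further Mycbp probe sets gave -0.74 (adjusted p = 0.0964), -0.23, -0.16 and 0.21. The Cd24a probe set that passed carries a name ending that marks a possible match to several transcripts.

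None of the 20 gene lists passed camera or fry's test for a shift in 1 direction in the bed nucleus. Fry's test for changes in either direction called 6, including the oestrogen-responsive (adjusted p = 0.00148) and ependymal lists (adjusted p = 0.0107). The list of oestrogen-responsive genes had 22 of 35 measured members higher and 13 lower (mean log2 difference 0.08, adjusted p = 0.227). No member passed over all probe sets, and 2 did adjusted over the list alone: Igfbp4, a binding protein of insulin-like growth factors, was at 0.86 ± 0.17, and Cck, the neuropeptide cholecystokinin, was at -0.80 ± 0.18. The steroid receptor and enzyme list had 10 higher and 9 lower members. Among its members, Esr1, oestrogen receptor alpha, was measured at an intensity of 10.7 ± 1.53 in long days and 14.0 ± 0 in short days, levels under the array median (0.40 ± 0.16, adjusted p = 0.312). The values of Esr2, oestrogen receptor beta (-0.17), Pgr, the progesterone receptor (-0.04), Oxt, oxytocin (-0.34, adjusted p = 0.346), and Avp, vasopressin (-0.21), did not pass either.

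Among the other functional lists in the bed nucleus, the members higher and lower were 9 and 12 for clock genes, 9 and 10 for thyroid, melatonin and other photoperiod genes, 22 and 14 for neuropeptides, and 8 and 9 for monoamine and nitric oxide genes. They were 7 and 12 for GABA and glutamate genes, 8 and 15 for immediate early genes, 12 and 9 for stress genes, 18 and 53 for the respiratory chain, and 14 and 32 for ribosomal proteins. For photoperiod, monoamine and astrocyte genes the mean lay above 0 and the median below it. Ndufc1, a subunit of respiratory complex I, was at 1.17 ± 0.28 and passed adjusted over the list alone. It read 331, 531 and 570 on the long-day arrays, and 703 and 1559 on the short-day arrays 4 and 5.

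Cell type markers in the bed nucleus were measured beside these genes. Ependymal and choroid plexus markers were lower in 7 of 8 members (mean -0.26, adjusted p = 0.117). Adjusted over the list alone 3 passed: the ciliary gene Rsph1 at -0.58, Otx2, a transcription factor of the choroid plexus, at -0.55, and the folate receptor Folr1 at -0.46. Their intensities were low. Rsph1 read 28, 34 and 26 in long and 18 and 21 in short days, and Otx2 23, 24 and 21 against 12 and 20. Folr1 read 24, 28 and 35 against 18 and 24, so its groups touched. Other members that passed adjusted over the list alone were the neuronal Map2 at -0.60, the myelin gene Mobp at -0.73, the pericyte receptor Pdgfrb at -0.50, the smooth muscle gene Tagln at -0.54 and the transcription factor Zic1 at -1.24. The Zic1 groups overlapped, with 278, 975 and 669 in long and 168 and 343 in short days. The members higher and lower were 11 and 5 for oligodendrocytes, 6 and 8 for astrocytes, 8 and 7 for microglia, 6 and 9 for vessels, 1 and 3 for red cells, 5 and 12 for neurons in general, 7 and 7 for striatal neurons, and 9 and 18 for hypothalamic neurons. No call for a list was made with an estimated correlation either.

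The bed nucleus calls depended on the arrays: with the spread taken from the bed nucleus arrays alone none passed, and without short-day array 4 or 5 of the bed nucleus 1 or 0 passed. Without short-day array 6 of the medial preoptic area 38 did. Without the long-day arrays 1, 2 and 3 of the bed nucleus the count was 16, 2 and 9. Without the long-day medial preoptic arrays 1, 2 and 3 it was 5, 6 and 2, and without the short-day medial preoptic array 4 it was 2. Some of the counts given here include probe sets that are not among the 10. Without the long-day bed nucleus array 1, 4 of the 16 were among them, and without its long-day array 3, 4 of the 9. Quantile normalization gave 5 higher and 2 lower probe sets against 4 and 6. Without the long-day bed nucleus array 1 there were 1 higher and 15 lower, and without its long-day array 3 there were 7 higher and 2 lower.

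In the medial preoptic area no probe set passed between short and long days with limma. Unadjusted p-values under 0.05 were found for 793 probe sets, 3.50% of those tested. The smallest p belonged to Cd24a, at a mean intensity of 413 ± 134 (SD, n = 3) in long days and 158 ± 45.0 (n = 3) in short days (-1.36 ± 0.24, adjusted p = 0.348). Other genes with small unadjusted p that did not pass were Ptgds, the prostaglandin D synthase of leptomeninges and choroid plexus (1.19), Kalrn, a synaptic guanine exchange factor (-0.84), Meis2, a homeodomain factor (-0.91), Crhr1, a receptor of corticotropin-releasing hormone (0.47), and Cacna2d3, a calcium channel subunit (-0.56). On the short-day arrays 4, 5 and 6 Meis2 read 296, 517 and 183, Kalrn 34, 39 and 20, and Ptgds 475, 383 and 915. Array 6 lay furthest from the long-day arrays for these genes and for Cacna2d3 (58, 64 and 54), but not for Crhr1 (22, 20 and 19). The immediate early gene Egr1 was at -0.63 and passed adjusted over its list alone, where 12 of 23 members were higher and 11 lower.

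All 14 measured striatal neuron markers were lower in the short-day medial preoptic samples, with a mean log2 difference of -0.27 ± 0.18 (SD over genes) and a camera adjusted p of 2.8e-06, although no member passed alone. With an estimated correlation the call was lost (adjusted p = 0.497), as it was with fry (adjusted p = 0.894). The members with the smallest p were Rgs9, a regulator of G-protein signalling (-0.67), Foxp1, a transcription factor (-0.42), Rasd2 (-0.49) and Ppp1r1b, which encodes DARPP-32 (-0.32). On the short-day arrays 4, 5 and 6 Rgs9 read 48, 67 and 32 and Rasd2 42, 45 and 27. Both were thus lowest on array 6, while Foxp1 and Ppp1r1b were not. The exact permutation test on the list mean per array gave p = 0.1, the smallest possible with 3 against 3 arrays. Hypothalamic and preoptic markers were higher in 21 of 27 members (mean 0.09, adjusted p = 0.0936). The short-day array 6 had the lowest striatal mean of the 11 arrays (5.43) and the highest hypothalamic mean (5.88).

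**Figure D2:**
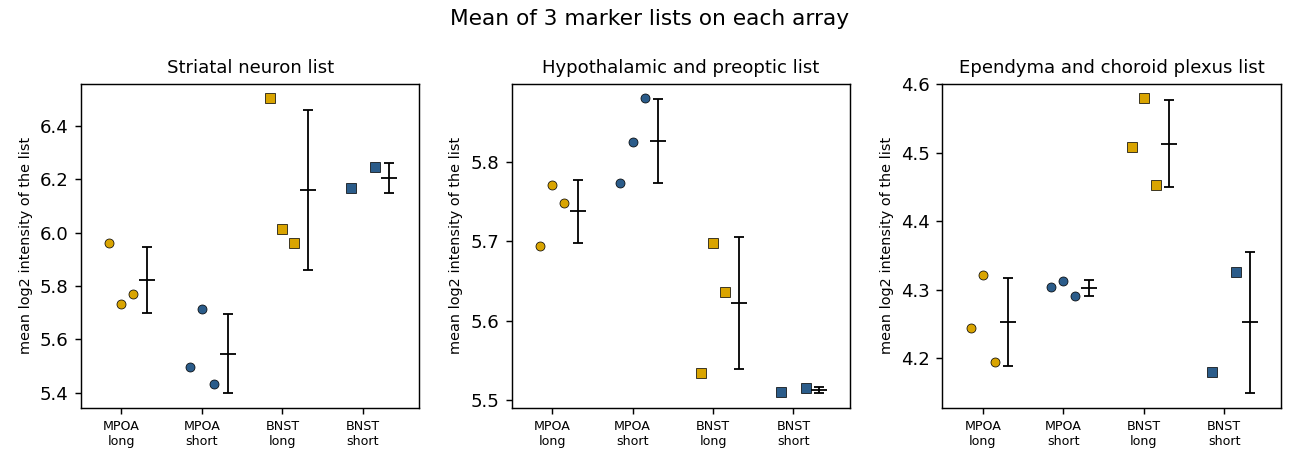
Mean log2 intensity (vertical axes) of the striatal, hypothalamic and ependymal marker lists on each array of the 4 groups; points are arrays, and the bar beside each group is its mean with the SD. The striatal mean on the medial preoptic arrays is 5.82 in long and 5.55 in short days; axes start above 0.

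The other lists did not pass camera or fry in the medial preoptic area. Oestrogen-responsive genes had 16 higher and 19 lower members (mean -0.02, adjusted p = 0.810), steroid receptors and enzymes 8 and 11, clock genes 11 and 10, photoperiod genes 8 and 11, neuropeptides 14 and 22, monoamine genes 7 and 10, and GABA and glutamate genes 8 and 11. Stress genes had 8 and 13, the respiratory chain 31 and 40, and ribosomal proteins 19 and 27. Ependymal markers had 5 higher and 3 lower members, oligodendrocyte markers 5 and 11, astrocyte markers 7 and 7, and microglial markers 6 and 9. Vascular markers had 6 and 9, red cell transcripts 1 and 3, and general neuronal markers 9 and 8. Mean and median differed in sign for GABA and glutamate, immediate early and stress genes. Esr1 (-0.01 ± 0.15), Esr2 (0.15 ± 0.14), Pgr (-0.24 ± 0.14), Gal, the neuropeptide galanin (0.26 ± 0.14), and Penk, proenkephalin (-0.31 ± 0.18), did not pass. With array weights, or without the long-day array 3, 1 probe set passed.

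**Figure D3:**
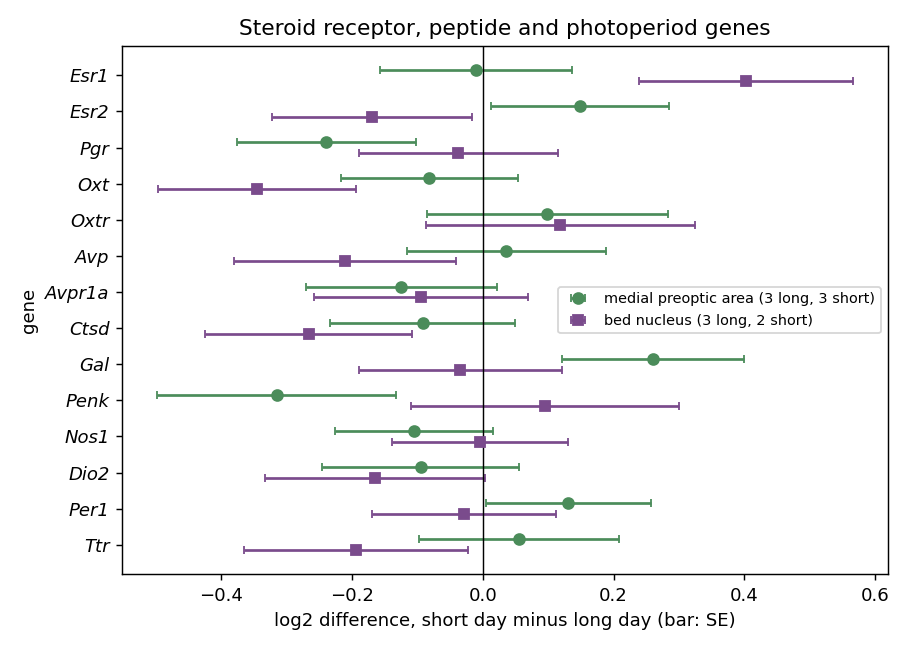
Log2 difference between short and long days (horizontal axis, bar is the SE) of 14 genes of steroid, peptide and photoperiod biology in the medial preoptic area (circles) and the bed nucleus (squares). None of them passed the threshold in either nucleus, and Esr1 in the bed nucleus was at 0.40.

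Averaged over both nuclei, Cd24a fell by 1.60 ± 0.18 on the log2 scale in short days (adjusted p = 4.9e-04, limma). That call was lost in 1 of 19 alternatives, the trended and robust prior (adjusted p = 0.122, limma). A further probe set of Cd24a fell by 0.88 ± 0.12 (adjusted p = 0.00699), and Lhx2 fell by 0.69 (adjusted p = 0.0334). The call for Lhx2 was lost in 11 of 19 alternatives, with an adjusted p of up to 0.371. On the medial preoptic arrays Lhx2 read 41, 51 and 38 in long and 38, 49 and 35 in short days. These 3 probe sets were the only ones to pass, and no gene list did. Of list members, Igfbp4 (0.47) and Cck (-0.47) passed adjusted over the list of oestrogen-responsive genes alone, and Adcyap1, the peptide PACAP (0.39), Cck and Nmb, neuromedin B (-0.37), passed adjusted over the neuropeptide list alone. The count was 1 with dim probe sets left out, 1 without the short-day bed nucleus array 5 and 5 without the long-day bed nucleus array 1.

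The test of whether the effect of day length differed between the nuclei gave no probe set past the threshold with limma, with 1888 unadjusted p-values under 0.05, and 5 passed without the long-day bed nucleus array 1. For Lhx2 the effect in the bed nucleus minus that in the medial preoptic area was -1.18 (adjusted p = 0.238), for Nptx2 -1.29, for Igha 1.20 and for Ptgds -2.30, all short of the threshold, and for Cd24a it was -0.49 ± 0.36 (adjusted p = 0.760). The effect on the striatal list differed between the nuclei (mean 0.32, adjusted p = 0.00316), with 13 of 14 members above 0, but not with an estimated correlation (adjusted p = 0.392). That on the ependymal list differed in the opposite direction (mean -0.31, adjusted p = 0.0469), with 8 of 8 members below 0, and again not with an estimated correlation (adjusted p = 0.260). Over all probe sets 0 members of either list passed, and adjusted over the list alone 0 striatal and 1 ependymal member did. Fry's test for changes in either direction called the photoperiod list (adjusted p = 6.0e-04). Adjusted over that list alone 0 members passed, and the list did not pass camera (adjusted p = 0.352) or fry's test for 1 direction (adjusted p = 0.513). Across the probe sets, which are not independent replicates, the effects in the 2 nuclei had a Pearson correlation of 0.05, which was -0.12 and -0.05 without the medial preoptic short-day array 6 and long-day array 2, and 0.13 without short-day array 5. A share of 0.65 of the 100 combinations of splits of the arrays within each nucleus gave a value as large.

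The nuclei themselves differed in 233 probe sets, of which 105 were higher in the bed nucleus and 128 higher in the medial preoptic area, in 188 named genes. Higher in the bed nucleus were Lhx2 (1.22 ± 0.11, adjusted p = 1.2e-05, limma), Arpp19, a regulator of protein phosphatase (1.39), the actin-binding tropomyosin Tpm1 (1.23), Kalrn (1.18), Coch (1.10) and Rasd2, a striatal GTPase (1.09). Also higher were Vim (1.05), the transcription factors Erf (1.05) and Mef2c (1.02), and the kinases Prkcd (1.02), Itpka (0.95) and Prkcb (0.94). Prkcd, protein kinase C delta, had mean intensities of 58.7 and 31.0 on the long- and short-day bed nucleus arrays and of 22.0 and 19.3 on the medial preoptic arrays. Higher in the medial preoptic area were Ache, acetylcholinesterase (-1.39 ± 0.15, adjusted p = 8.4e-05, limma), the calcineurin subunit Ppp3cb (-1.17), Car10 (-0.99), the RNA-binding proteins Elavl4 (-0.94) and Nova1 (-0.80). Others were the synaptic syntaxin Stx1a (-0.93), Flot2 (-0.89), Itih3 (-0.85), Sparc (-0.84), the kainate receptor subunit Grik1 (-0.84), Cbarp (-0.82) and the arginine transporter Slc7a3 (-0.78). The probe sets behind Cbarp, Flot2, Stx1a, Vim and the imprinted gene Ndn carry the name ending that marks a possible match to several transcripts.

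**Figure D4:**
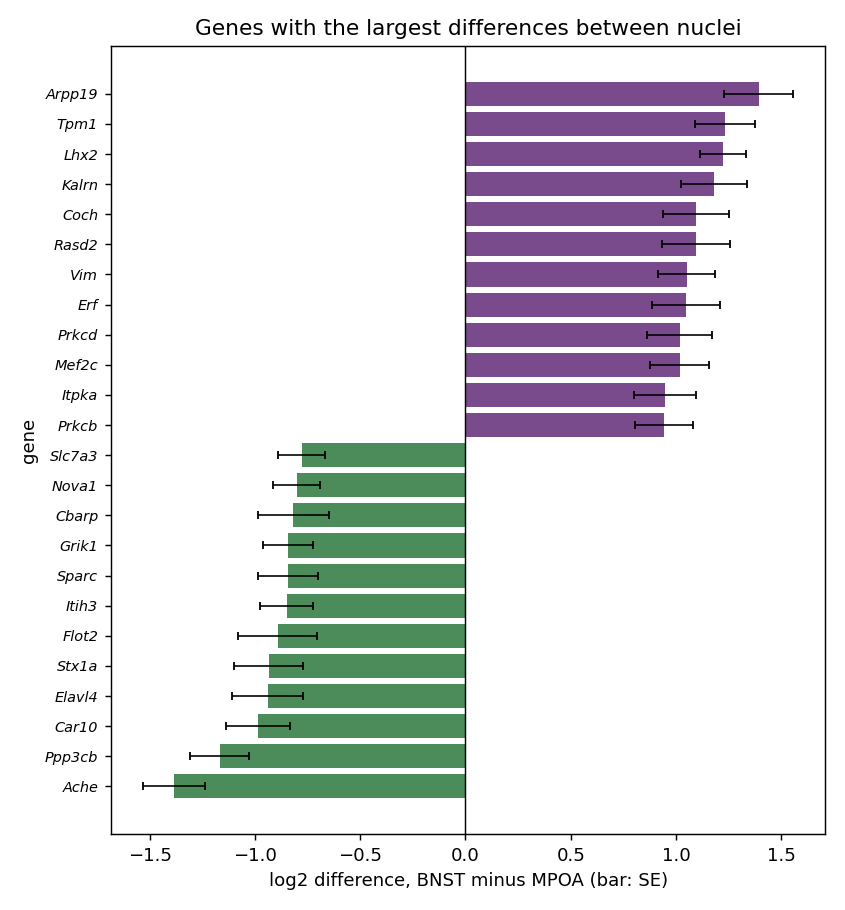
Log2 difference, bed nucleus (BNST) minus medial preoptic area (MPOA) (horizontal axis, bars with SE), of the 12 genes with the largest positive and the 12 with the largest negative difference among those that passed. Lhx2 is at 1.22 and Ache at -1.39.

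Striatal neuron markers were higher in the bed nucleus in 13 of 14 members, with a mean of 0.50 ± 0.31 (SD over genes, adjusted p = 4.5e-13). The list call was lost with an estimated correlation (adjusted p = 0.103). Of the members, 6 passed over all probe sets, including Foxp1 (0.80), Rgs9 (0.71) and Ppp1r1b (0.58), and 11 adjusted over the list alone. Hypothalamic and preoptic markers were lower in the bed nucleus in 23 of 27 members (mean -0.21, adjusted p = 7.0e-07), and this call held with an estimated correlation (adjusted p = 0.0157). Of its members 7 passed over all probe sets and 11 adjusted over the list alone. Gal was at -0.65 ± 0.10, from 95.7 and 115 in the medial preoptic groups to 67.3 and 67.0 in the bed nucleus groups. The LIM factors Lhx8 (-0.75) and Lhx1 (-0.72) and the imprinted genes Ndn (-0.58) and Nnat (-0.50) were lower too, while Otp passed in the other direction (0.52). The calls for Otp and Rgs9 were lost in 12 and 10 of 19 alternatives.

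The respiratory chain list was lower in the bed nucleus in 56 of 71 members (mean -0.13, adjusted p = 7.0e-07, and adjusted p = 0.232 with an estimated correlation), and general neuronal markers in 12 of 17 (mean -0.14, adjusted p = 0.00777, and adjusted p = 0.103 with an estimated correlation), of which Gap43, a growth cone protein, passed over all probe sets (-0.48). Oligodendrocyte markers were higher in 11 of 16 (mean 0.17, adjusted p = 0.0220, and adjusted p = 0.103 with an estimated correlation), with Mbp, myelin basic protein, at 0.88 and Cnp at 0.39. In lists that did not pass, single members did: the immediate early gene Egr1 (0.80), the glucocorticoid-induced kinase Sgk1 (0.72), the AMPA receptor subunit Gria3 (0.78), the steroid receptor coactivator Ncoa1 (0.52) and the opioid peptide gene Pdyn (0.42) were higher in the bed nucleus. The calls for Ncoa1 and Pdyn were each lost in 12 of 19 alternatives. Esr1 (0.07), Esr2 (0.05) and Pgr (-0.08) did not differ past the threshold. The 3 prime to 5 prime ratio of actin averaged 4.87 and 5.29 on the long- and short-day medial preoptic arrays, and 3.97 and 4.38 on those of the bed nucleus. For Gapdh the averages were 6.17 and 6.45 against 5.75 and 5.31. Whether RNA quality contributed to the differences between the nuclei was not tested.

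The remaining lists did not pass camera between the nuclei, while fry called the stress list (adjusted p = 0.00190). The members higher and lower in the bed nucleus were 10 and 9 for steroid receptors and enzymes, 19 and 16 for oestrogen-responsive genes, 14 and 7 for clock genes, 10 and 9 for photoperiod genes, 14 and 22 for neuropeptides, 9 and 8 for monoamine genes and 6 and 13 for GABA and glutamate genes. They were 15 and 8 for immediate early genes, 15 and 6 for stress genes, 6 and 8 for astrocytes, 6 and 9 for microglia, 10 and 5 for vessels, 3 and 1 for red cells, 7 and 1 for ependyma and 23 and 23 for ribosomal proteins. The count of 233 was 70 and 120 without the short-day bed nucleus arrays 5 and 4, and 104 without the long-day bed nucleus array 1. It was 98 and 138 without the long-day medial preoptic arrays 2 and 3, and 152 without the short-day medial preoptic array 5.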

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

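Of the tests in this part, those on the short-day medial preoptic array 6, both for the striatal list and for the array itself, were chosen after the result was seen. The added marker lists were written after the differences they address had been seen, but before any result for those lists. Adjusting their p over the 5 added lists, which decides the reading of the further striatal list, was chosen after the values were seen. Differences of gene lists between the nuclei are given here because the test of the difference itself passed, and the control probe set because it lies outside the measured genes.

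The effect of day length on 2 marker lists differed between the nuclei with camera at the preset correlation. Striatal markers had a mean difference of 0.32 (bed nucleus minus medial preoptic area), and ependymal and choroid plexus markers had one of -0.31. Neither call held with an estimated correlation.

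A control probe set for the 5 prime end of 18S ribosomal RNA read 123 on the short-day medial preoptic array 6, against 18 to 26 on the other 10 arrays.

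The probe sets lower on the short-day bed nucleus arrays include Cd24a, Vim and Lhx2. RNA integrity as read by actin is not decided by a test with the actin ratio as a covariate. The ratio overlapped between the bed nucleus groups (3.97 ± 0.17, SD, in long and 4.38 ± 0.76 in short days), so the covariate could change little. With it the median log2 difference of the 6 lower probe sets was -1.21 against -1.14 without it, and 6 probe sets in all passed against 10. Tissue of the ventricular lining in the long-day punches may have contributed: a list of 22 measured ventricular zone and neuroblast genes, none of them among those that passed, was lower (mean -0.21, limma camera adjusted p = 0.0105 over 5 added lists), but not past the threshold with an estimated correlation (adjusted p = 0.0900). Sox11, Sox4 and Id3 passed adjusted over that list alone, while Stmn1 (-0.20), Tubb2b (0.01) and Dcx (-0.01) did not, and 16 of the 22 lie above the array median. Thalamic tissue cannot be told apart (mean -0.24 over 17 measured genes, limma camera adjusted p = 0.199, with 13 lower and 4 higher), and an effect of day length itself was not tested and stays open.

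Striatal markers were lower on the short-day medial preoptic arrays with camera at the preset correlation, a call that was lost with an estimated correlation (adjusted p = 0.497) and with fry (adjusted p = 0.894). The short-day array 6 alone is argued against, since without it the mean of the list was -0.22 against -0.27 with it. The list means of the short-day arrays 4 and 5 were 5.50 and 5.71, against 5.96, 5.73 and 5.77 on the long-day arrays 1, 2 and 3. Array 5 thus lay close to the long-day arrays, and the remaining difference rests largely on array 4. Less striatal tissue in the short-day punches cannot be told apart: a further list of 17 measured striatal genes, which shares none with the first, had 13 lower members and a mean of -0.10. Its camera p met the criterion set beforehand (0.0247) but not when adjusted over the 5 added lists (limma camera adjusted p = 0.124). An effect of day length on striatal-type neurons was not tested and stays open.

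The short-day medial preoptic array 6 stands apart from the other 10 arrays in its first principal component and in its residual SD, which was 0.197 against 0.134 to 0.166. Additional ribosomal RNA in the labelled sample cannot be told apart, because the 18S probe sets disagree. The 5 prime and 3 prime ones read 123 and 355, against 18 to 26 and 101 to 143 on the other 10 arrays. These readings are 97 and 212 above the highest other array. The middle one read 4115, within the range of the other arrays (3276 to 5595, a span of 2319). A rise by as many intensity units would be hidden there. A rise by the same factor as at either end would have put it above that range, where it did not lie. Degraded RNA cannot be told apart either, because the 3 prime to 5 prime ratio of actin was 6.63 against 3.84 to 5.42, while that of Gapdh was 6.40, within the range of 5.24 to 6.64. A difference between this sample and the others of its group that is biological was not tested.

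For the bed nucleus, 2 of the 10 splits of its 5 arrays gave at least as many probe sets, the real one included. The real split gave 10 and the highest other 14, and 10 splits are too few for a share under 0.05. For the medial preoptic area all 10 splits gave 0, the real one and the highest other included, which decides nothing, and their number is again too small. For the mean of both nuclei chance cannot be excluded, as 14 of 100 splits gave at least the real count of 3 and the highest gave 157. For the difference between the nuclei the real count is 0, which all 100 splits reach by construction, so they decide nothing there; the highest other gave 157. Between the nuclei chance is argued against: only 1 of 100 splits, the real one, gave 233, and the highest other gave 47. The 100 splits are a draw, and those not drawn were not checked.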

How the results depend on the processing

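Alternatives were fixed before the data were examined, except the noise that undoes the rounding, which was chosen after seeing the data. Centring on the median changed nothing, since every array has the same median, so it says nothing about stability. No result that passed changed direction under any alternative, and unless stated the cause of a change was not tested. For the bed nucleus the count of 10 was 0 with its own 5 arrays alone, where fewer arrays give the spread, 30 at a threshold of 0.10 and 0 to 38 with arrays left out in turn, where a lone short-day array is assumed to vary like the other groups. It was 0 and 1 without its short-day arrays 5 and 4, 16 and 2 without its long-day arrays 1 and 2, 5, 6 and 2 without the long-day medial preoptic arrays 1, 2 and 3, and 2 and 38 without the short-day medial preoptic arrays 4 and 6. Of its 9 genes, 0 passed under every alternative: the calls were lost in 3 (Lhx2) to 13 (Mycbp) of 19 or 20, and for 6 genes (Mycbp, Mycn, Nrros, Vim, Nptx2 and Rela) at least as often as they were kept. For the medial preoptic area the count of 0 was 1 with array weights and 0 to 1 with arrays left out, 1 without its long-day array 3. For the mean of both nuclei the count of 3 was 1 with the filter on dim probe sets and 1 to 5 with arrays left out, 1 without the short-day bed nucleus array 5 and 5 without the long-day array 1. For the difference between the nuclei the count of 0 was 0 to 5, 5 without the long-day bed nucleus array 1. Between the nuclei the count of 233 was 402 at a threshold of 0.10 and 70 to 224 with arrays left out, 70 and 120 without the short-day bed nucleus arrays 5 and 4, 104 without the long-day array 1, 98 and 138 without the long-day medial preoptic arrays 2 and 3, and 152 without the short-day array 5. Of the 41 genes named there that passed, 23 passed under every alternative. With rounding noise the median counts over 20 draws were 0, 11, 3, 0 and 230.5 in the order of the comparisons. With an estimated correlation the adjusted p was 0.497 for the striatal list in the medial preoptic area, 0.392 and 0.260 for the striatal and ependymal lists in the difference between the nuclei, and, between the nuclei, 0.103 for the striatal, neuronal and oligodendrocyte lists and 0.232 for the respiratory chain. With fry it was 0.894, 0.512 and 0.114 for those first lists and 0.0503 for the respiratory chain, while the stress list between the nuclei was gained (0.00190). Fry's test for changes in either direction called 6 lists in the bed nucleus, 1 for the difference and 11 between the nuclei. With the mean of all probe sets of a gene it was 0.0968 for the ependymal and 0.197 for the oligodendrocyte list, and with dim probe sets left out 0.119 for the ependymal, 0.132 for the oligodendrocyte and 0.0886 for the neuronal list, where fewer genes were tested. With arrays left out it ranged from 0.0146 to 0.185 for the ependymal list and from 7.3e-08 to 0.0890 for the striatal list in the difference between the nuclei, and from 0.00586 to 0.0935 for the oligodendrocyte list. Whether the sample numbers pair the samples across the nuclei is not given and stays open. The deviations of the same-numbered arrays correlated at 0.01, -0.01, 0.10, 0.12 and -0.02, and not every array correlated best with its own number. The medial preoptic arrays 3 and 4 did (0.10 against at most 0.04, and 0.12 against at most 0.06). Such values from 2 or 3 arrays per group cannot show that same-numbered samples came from different animals. With the sample number as a fixed replicate block 225 probe sets passed between the nuclei (183 shared) and 0 for the difference, and the adjusted p of the ependymal list was 0.107. As a random block, whose estimated correlation was 0.00786, it gave 10 in the bed nucleus, 3 for the mean and 0 in the medial preoptic area, which says nothing about stability. Low signal limits what can be seen, since 51.1% of values lie at or under 19, where a step of 1 intensity unit is 0.07 or more on the log2 scale.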

Other observations

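The tests in this part were all chosen after the results were seen. On the short-day bed nucleus arrays, 15 of 21 measured proliferation genes were lower (mean -0.05, limma camera adjusted p = 0.788), as were 9 of 17 genes of the meninges (mean -0.03, limma camera adjusted p = 0.987). The transcription factor Tcf7l2 (-1.13) and the adhesion molecule Ntng1 (-1.30) were among 5 thalamus list members that passed adjusted over the list alone there, 4 lower and Grid2ip higher (0.39). In the medial preoptic area the ventricular zone and neuroblast list had 12 higher and 10 lower members, the proliferation list 11 and 10, the thalamus list 10 and 7, and the meninges list 6 and 11. Between the nuclei the further striatal list was higher in the bed nucleus in 12 of 17 members (mean 0.20, limma camera adjusted p = 1.9e-04). That call was lost with an estimated correlation (adjusted p = 0.110).

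Probe sets whose names mark a possible match to several transcripts were set against the others after many of them appeared in the split described next. The 1511 such probe sets lay 0.02 above the others on the short-day bed nucleus arrays, which did not pass (camera p of 0.404 with an estimated correlation). Between the nuclei they lay at -0.03 against the others, which did not pass either (camera p of 0.0913 with an estimated correlation), and made up 12.2% of the probe sets lower and 3.26% of those higher in the bed nucleus at an unadjusted p under 0.01, against 6.68% of all. With the actin ratio as a covariate, the median log2 difference of the 4 probe sets higher on the short-day than on the long-day bed nucleus arrays was 0.92, against 0.94 without it.

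With the medial preoptic arrays 1, 3 and 6 set against 2, 4 and 5 and the bed nucleus groups kept, 157 probe sets passed for the mean of both nuclei, 93 higher and 64 lower, against 3 for the real groups. This is the highest of the 100 splits. A count many times the real one points to a structure of the samples, which was not tested and is not established by a split chosen for its size. Because the bed nucleus kept its day-length groups, their difference contributes to the 157, and the split called 0 probe sets in the medial preoptic area alone, as the real groups did. Genes with the smallest p in that split, named after their values were seen, were Lhx2 (-0.77), Hmgb2 (-0.66) and Igha (0.69).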
